A study of Rattus norvegicus with 4 samples.

How the data were processed

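Droplet single-cell RNA-seq of rat blood was analysed, with 1 library each for Sham, SCI, MSC-i.t and MSC-i.v. The deposited values are UMI counts per gene and barcode, written by Cell Ranger 4 per the file headers, and they list 25340 genes by 6794880 barcodes per library, so no cells had been removed. The genome build is mRatBN7.2 per the submitters' processing notes, while some gene names in the deposited lists belong to an older rat assembly, so no coordinates are given. The labels' protocol describes a bulk poly(A) preparation, which the single-cell matrices do not match; nothing was taken from it. Symbols of the fixed gene lists were looked up in the deposited gene lists and, failing that, through synonyms in a RefSeq gene table of assembly GRCr8.

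Barcodes with at least 500 UMIs, at least 200 genes and at most 20% of UMIs from mitochondrial genes were kept. Doublets were called per library with Scrublet as implemented in scanpy 1.11.5 and removed. The 4 libraries were clustered together in scanpy on counts per 10000 after log transformation, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), without batch integration, since library and group coincide. Clusters were named from markers fixed before the data were examined, as the class with the highest mean marker score. A cluster stayed unnamed with fewer than 3 detected markers, a median doublet score at or over 0.15, no class with a score above 0, a median of UMIs far below its libraries' without markers of its own, or, for platelet and erythroid clusters, a leukocyte marker score over 0.25; these thresholds were set after the data were seen. Classes were compared between libraries only where no cluster of the class had more markers of another class than of its own among its 10 leading genes, which T-like, NK-like and monocyte-like cells met. Lymphocytes in the neutrophil ratio are T-like, B-like and NK-like cells.

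Shares were taken over leukocytes, the kept cells outside platelet-like, erythroid-like and unnamed clusters, with exact Clopper-Pearson 95% intervals. UMIs were summed per library and class and divided by the class total to give CPM, with exact Poisson intervals, and ratios of 2 libraries have exact conditional binomial intervals. Where a library had 0 UMIs, a floor of 3 counts was used and the ratio is a bound at that floor, not an exact limit. The CPM of the sex-linked genes are over all kept cells. Intervals cover counting error only, since cells are not replicates; no p-values were computed, and a ratio compares a pair of libraries, not conditions. For SCI over Sham, CPM scaling left a median log2 ratio over well-counted genes of 0.09 in T-like, 0.07 in NK-like and 0.15 in monocyte-like cells, relative to which ratios should be read. Gene lists fixed before the data were examined were summarised by the median log2 ratio of members with at least 10 UMIs, and by its percentile among 10000 random lists of the same size matched on expression; a list stood apart at or under percentile 1 or at or over percentile 99.

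Named genes followed a rule fixed before the data were examined. In each of the 3 classes and each comparison they are the 4 highest and 4 lowest ratios among genes with at least 50 UMIs in one library and UMIs in at least 5% of its cells, leaving out genes without their own symbol, mitochondrial, ribosomal, hemoglobin, immunoglobulin and T cell receptor segment genes, sex-linked genes and cell type markers. Members of lists that stood apart are named as the 2 highest and 2 lowest with at least 50 UMIs; the lists described were picked after their values were seen. Of the genes that these rules name, 2 are not reported here. Other genes in sentences on clusters, doublets and figures were picked after their values were seen.

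The ratio and list steps and the naming of clusters were tested on simulated data drawn from the class profiles, with 50 genes changed at each fold size among 8705. For SCI over Sham in T-like cells, intervals held the true ratio for 94% of genes at a fold of 4, 96% at 2, 92% at 0.5, 92% at 0.25 and 95.3% of unchanged genes. Median recovered folds were 3.96, 1.99, 0.493 and 0.251 for the changed genes. Of 200 unchanged lists, 1% lay at or over percentile 99 and 1.5% at or under percentile 1, and of 200 lists raised 1.25-fold, 100% lay at or over percentile 99. Each gene was drawn independently, so lists whose members move together were not tested. Apart from the changed genes, both libraries were drawn from a shared profile with counting error only. Real log2 ratios of SCI over Sham in T-like cells had an SD of 0.50 over well-counted genes. The percentages of intervals and lists above therefore need not hold for the real libraries. Simulated T-like, NK-like and monocyte-like cells received the right name in 100%, 99.9% and 100% of cases. They were drawn from the profiles of classes already named by the same markers, without doublets. This therefore does not test whether real clusters are named rightly.

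Alternatives fixed before the data were examined were minima of 250 and 1000 UMIs, a library-specific minimum, a mitochondrial limit of 10%, no doublet removal, resolutions of 0.5 and 2, variable genes chosen within libraries, class by per-cell marker score, all kept cells as denominator, cells thinned to 500 UMIs, TMM scaling (edgeR 4.0.16), DESeq2 1.42.0 size factors, the mean over cells, subtraction of free RNA (the profile of barcodes with 10 to 100 UMIs, scaled by hemoglobin), and other count filters. Added after the data were seen were Sham as reference in place of SCI, an equal doublet rate of 0.8% per 1000 cells, clustering without 707 genes that set SCI apart, subtraction of the ratio in erythroid-like cells, with and without a limit to genes beyond free RNA, and monocyte-like cluster 12 alone. Those 707 genes lay at least 2-fold higher, or at least 2-fold lower, in SCI T-like cells than in T-like cells of each other library. At the equal doublet rate, the share of cells removed grew with the number of cells in a library. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3 were used.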

Results

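Single-cell RNA-seq libraries were made from rat blood, with 1 library in each of 4 groups. Per the labels, the study used 40 rats, 10 in each group: a sham group (Sham), a group with traumatic spinal cord injury (SCI), and a pair of injured groups given umbilical cord mesenchymal stromal cells (MSC). These cells were delivered into the spinal canal (MSC-i.t, 10000000 cells/kg) or into a vein (MSC-i.v, 30000000 cells/kg), on 2 occasions, 72 hours and 7 days after the injury. The time of the blood draw and the number of rats behind each library are not stated in the labels, and the names of the deposited data sets carry another time tag for SCI than for the other 3 libraries. The libraries held 71648050 UMIs (unique molecular identifiers, each standing for 1 captured RNA molecule) in Sham, 63133881 in SCI, 80115646 in MSC-i.t and 91124523 in MSC-i.v. After filtering, 10230 cells remained in Sham, 7964 in SCI, 10958 in MSC-i.t and 15589 in MSC-i.v, with medians of 5029, 5845, 5523.5 and 3668 UMIs per cell. There were no replicate libraries, so no difference below was tested; intervals are exact 95% intervals for counting error only, and gene levels are CPM, the UMIs of a gene scaled to a fixed total of UMIs summed over the cells of a class.

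The cells formed 26 clusters. T-like cells were the largest leukocyte class in every library. NK-like and monocyte-like cells, and B-like clusters 6, 8 and 19, came next, while platelet-like and erythroid-like cells were left out of the leukocyte totals. B-like cells were compared cluster by cluster, because the leading genes of cluster 6 held more dendritic than B cell markers (*Cd74* and *RT1-Da*). NK-like cluster 14 had an NK marker score of 3.84, whereas NK-like cluster 20 scored 0.98 for NK and 0.51 for T cell markers. Cluster 20 held 38.0% of NK-like cells in Sham, 42.5% in SCI, 50.3% in MSC-i.t and 41.3% in MSC-i.v. NK-like values below may therefore include T cells. Clusters left without a name, of which 4 had high doublet scores and cluster 10 held platelet and leukocyte markers together, made up 7.68% of kept cells in Sham, 1.68% in SCI, 7.01% in MSC-i.t and 3.61% in MSC-i.v. Doublet calling worked unevenly, marking 0.0195% of cells in Sham, 1.74% in SCI, 0% in MSC-i.t and 6.60% in MSC-i.v. Neutrophil-like cells were almost missing from all 4 libraries, with 24, 5, 9 and 29 cells, and the labels do not say whether granulocytes were removed before loading. Their number per 1000 lymphocytes was 3.35 (2.14 to 4.98) in Sham, 0.760 (0.247 to 1.77) in SCI, 1.06 (0.482 to 2.004) in MSC-i.t and 2.63 (1.76 to 3.77) in MSC-i.v. Under other settings that number ran from 1.17 to 9.68 in Sham and from 0.110 to 4.01 in MSC-i.t, and the leading genes of this cluster included the basophil gene *Mcpt8*. *Eif2s3y*, a Y-linked gene, was at 89.8, 87.8, 92.5 and 82.1 CPM in Sham, SCI, MSC-i.t and MSC-i.v. *Kdm5d*, another, was at 19.5, 22.9, 20.9 and 17.1 CPM. *Ddx3y* had 0 UMIs in each library, which at the floor of 3 counts allows up to 0.0607 CPM in SCI, and *Usp9y* had 1 UMI, in Sham. Hemoglobin transcripts made up 14.1% of kept UMIs in Sham, 7.86% in SCI, 9.82% in MSC-i.t and 17.4% in MSC-i.v.

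**Figure D1:**
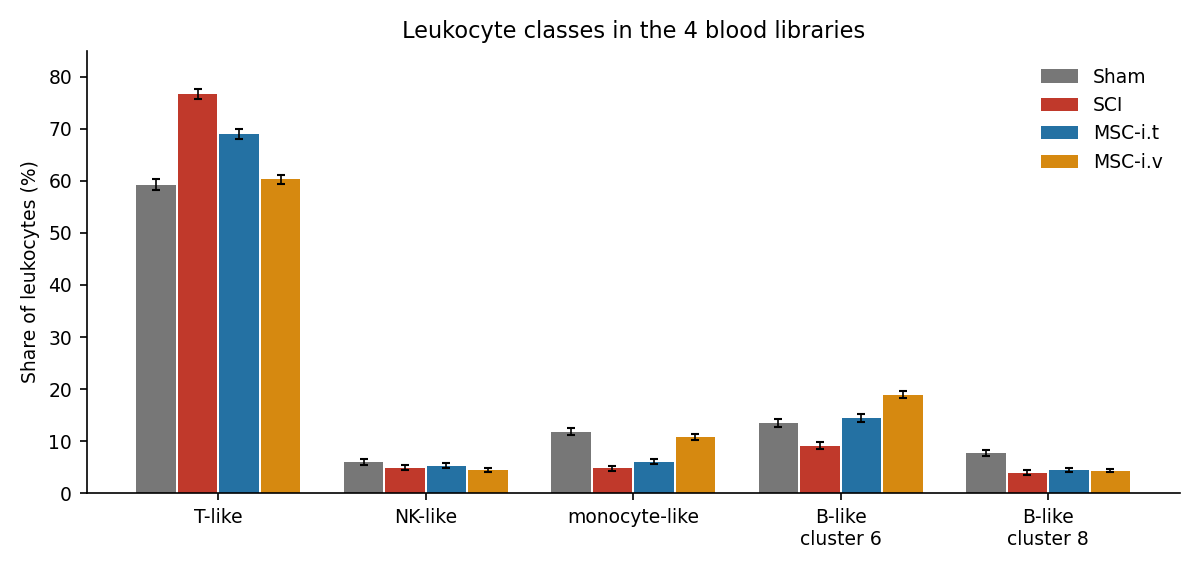
Share of leukocytes (%, y axis) held by 3 leukocyte classes and 2 B-like clusters in the Sham, SCI, MSC-i.t and MSC-i.v libraries; error bars are exact 95% binomial intervals. T-like cells range from 59.2% in Sham to 76.7% in SCI, and monocyte-like cells from 4.76% in SCI to 11.8% in Sham.

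SCI against Sham addresses what injury to the cord does to circulating immune cells. The SCI library was richer in T-like cells than the Sham library, and poorer in monocyte-like cells and in cells of each of B-like clusters 6, 8 and 19. In SCI monocyte-like cells most MHC class II genes were far lower, and most type I interferon and immediate early genes higher. A further group of 83 genes was several times higher in SCI T-like cells. Its members with enough UMIs were also higher in the other classes examined, among them 20 members in erythroid-like cells.

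T-like cells made up 59.2% (58.2 to 60.3) of Sham leukocytes and 76.7% (75.7 to 77.7) of SCI leukocytes, a log2 ratio of 0.37. Monocyte-like cells made up 11.8% (11.1 to 12.5) in Sham and 4.76% (4.27 to 5.29) in SCI, a log2 ratio of -1.31. The larger part of that gap lay in monocyte-like cluster 21, led by *Fcnb*, *Fn1* and *Vcan*, with 4.66% (4.22 to 5.14) in Sham and 0.750% (0.560 to 0.982) in SCI. Monocyte-like cluster 12, led by *Fcgr3a* and *Csf1r*, held 7.14% in Sham and 4.01% in SCI. *Cebpb*, much higher in SCI than in Sham monocyte-like cells, is also among the leading genes of cluster 12. The split between clusters 12 and 21 was not checked under other clusterings. NK-like cells made up 6.004% (5.50 to 6.54) in Sham and 4.92% (4.42 to 5.45) in SCI. B-like cluster 6 held 13.5% in Sham and 9.08% in SCI, and B-like cluster 8 held 7.72% and 3.88%. Cluster 19, led by the precursor B cell genes *Igll1*, *Rag1* and *Dntt*, held 1.04% (0.829 to 1.28) in Sham and 0.274% (0.165 to 0.428) in SCI.

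Within monocyte-like cells, the MHC class II list had a median log2 ratio of -1.62, below every one of the 10000 random lists matched on expression. *RT1-Bb* was at 12.1 CPM (7.66 to 18.1) in SCI and 122 CPM (114 to 131) in Sham, a log2 ratio of -3.34. *RT1-Db1* was at 56.8 CPM (46.6 to 68.5) in SCI and 455 CPM (439 to 472) in Sham, a log2 ratio of -3.00, and *RT1-Ba* at 58.3 and 275 CPM. All 3 also lead B-like cluster 6. In the same monocyte-like cells the B cell marker *Cd79b* was at 41.5 CPM in SCI and 92.4 CPM in Sham, while *Cd79a* was at 5.78 and 3.53 CPM. The list's members *Ctss* and *Lgmn* went the other way or hardly differed, with log2 ratios of 0.75 and 0.03. In cluster 12 alone the list's median was -0.95. The type I interferon list was higher in SCI monocyte-like cells (median log2 ratio 0.76, percentile 100), led by *Irf7* (1.88) and *Herc6* (1.45), whereas *Rsad2* (-1.84), which is abundant in erythroid-like cells, and *Ifi44l* (-0.68) were lower. Immediate early genes had a median of 0.85, with *Jund* at 2.28 and *Dusp1* at 1.21, against *Myc* at -0.75 and *Jun* at -0.39. In cluster 12 alone these medians were 0.44 for the type I interferon list and 0.39 for immediate early genes, and *Jund* was at -0.17 in monocyte-like cells once the ratio in erythroid-like cells was subtracted.

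**Figure D2:**
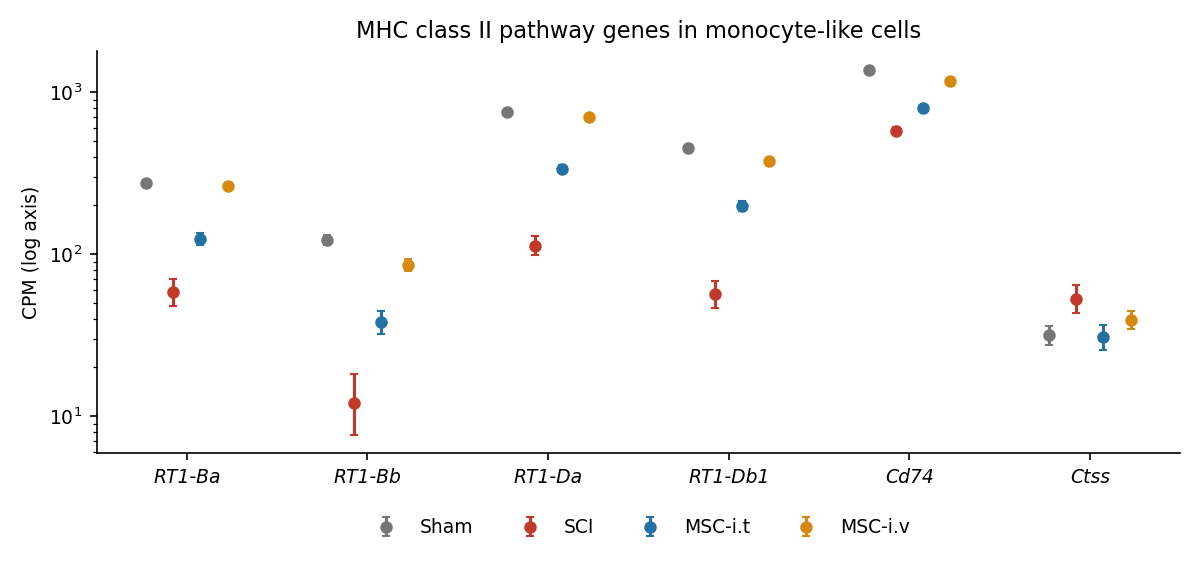
Levels of 6 MHC class II pathway genes in monocyte-like cells (CPM, log axis) in the 4 libraries, with exact 95% Poisson intervals. *RT1-Bb* lies at 12.1 CPM in SCI, 38.2 in MSC-i.t, 86.0 in MSC-i.v and 122 in Sham, and *Ctss* is highest in SCI, at 53.1 CPM.

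In T-like cells, held mostly by clusters 5 and 9 in SCI and by clusters 3, 9 and 5 in Sham, the naive and central memory list was higher in SCI (median log2 ratio 0.30, percentile 99.96). With the ratio in erythroid-like cells subtracted the median lay below 0, but only members with at least 20 UMIs there have such a ratio. *Klf2*, *Tcf7*, *Txk* and *Actn1* have none, so that value comes from other members and does not correct the list as a whole. *Klf2*, at 31.9 CPM in SCI and 2.39 CPM in Sham (log2 ratio 3.74), also belongs to a set of 83 genes at least 4-fold higher in SCI T-like cells. It was at 0 CPM in erythroid-like cells of both libraries. *Tcf7* had a log2 ratio of 0.70, while *Txk* was at -0.01 and *Actn1* at 0.09. The MHC class II list was lower in SCI T-like cells (median -0.54), with *RT1-Bb* at -1.09 and *Cd74* at -1.04, and *Ctss* at 0.20 and *RT1-DOb* at 0.09. *RT1-Bb* and *Cd74* also lead B-like cluster 6, and *RT1-Bb* was at only 2.12 CPM in SCI and 4.52 CPM in Sham T-like cells. Cluster 6 held 9.08% of leukocytes in SCI and 13.5% in Sham, and the B cell activation list was also lower in SCI T-like cells, with a median of -0.19. Once the ratio in erythroid-like cells was subtracted, the MHC class II list of T-like cells no longer stood apart. That value leaves out *RT1-Bb*, *Ctss* and *RT1-DOb*, which had too few UMIs in erythroid-like cells, so it does not show that the difference went away. In NK-like cells the cell cycle list was higher in SCI (median 0.77, percentile 100). Its members *Mcm5* (2.39) and *Mcm2* (1.18) had the largest log2 ratios, and *Mki67* (0.54) and *Mcm7* (0.58) the smallest among the well-counted ones. Nuclear-encoded oxidative phosphorylation genes were slightly lower in SCI, with medians of -0.20 in T-like, -0.11 in NK-like and -0.28 in monocyte-like cells, but with the ratio in erythroid-like cells subtracted they were at 0.12 in T-like and 0.25 in NK-like cells. Of 75 pairs of a list and a class, 10 stood apart as higher in SCI and 24 as lower, where 1.5 would do so for lists of unrelated genes. Members of a list may move together, and the classes come from the same libraries, so the excess does not measure significance. With the ratio in erythroid-like cells subtracted these counts were 5 and 7, and on genes beyond free RNA 1 and 5. In both, fewer lists and fewer members had a value, so the fall is not the effect of the subtraction alone. Platelet and hemoglobin transcripts were among the lower ones in T-like cells, with medians of -1.38 and -1.07.

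*Dapk3* was among the 4 highest single-gene ratios in T-like, NK-like and monocyte-like cells, and *Sap30l* in the first 2 of these. In T-like cells *Dapk3* was at 64.6 CPM (61.9 to 67.4) in SCI and 3.05 CPM (2.42 to 3.802) in Sham, a log2 ratio of 4.40. *Bloc1s3* (4.26), *Sap30l* (4.24) and *Pura* (4.04) followed. The lowest were *Fcnb* (-2.78), *Ifi27* (-1.94, 202 CPM in SCI and 773 CPM in Sham), *Pla2g2a* (-1.92) and *Hopx* (-1.50), of which *Pla2g2a* was at 0.44 and *Hopx* at 0.11 once the ratio in erythroid-like cells was subtracted. *Fcnb* and *Hopx* also lead monocyte-like cluster 21, and *Pla2g2a* leads platelet-like cluster 15. NK-like cells had *Lmnb1* (4.31), *Dapk3* (4.00), *Sap30l* (3.99) and *Basp1* (3.86) at the top, and *Lgals5* (-3.34), *Tmcc2* (-2.50), *Tubb2a* (-2.48) and *Car2* (-2.12) at the bottom; *Lgals5*, *Tmcc2* and *Car2* are abundant in erythroid-like cells and *Tubb2a* leads platelet-like cluster 15. In monocyte-like cells *Cebpb* was at 1933 CPM (1871 to 1996) in SCI and 82.6 CPM (75.9 to 89.7) in Sham, a log2 ratio of 4.55. *Dapk3* (4.18), *Cdv3* (3.87) and *Rnf149* (3.74) came next, and *Tmcc2* (-2.24) and *RT1-Ba* (-2.23) were lowest after *RT1-Bb* and *RT1-Db1*. The SD of log2 ratios over genes was 0.50 in T-like cells for SCI over Sham, against 0.21 for MSC-i.t over Sham and 0.20 for MSC-i.v over Sham. A set of 83 genes, taken as at least 4-fold higher in SCI T-like cells, summed to 3898 CPM there in SCI, 645 CPM in Sham, 573 CPM in MSC-i.t and 707 CPM in MSC-i.v. The same set summed to 181 CPM in SCI erythroid-like cells and 31.7 CPM in Sham ones. With SCI and Sham each in a single library, injury and anything else that set this library apart cannot be separated.

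**Figure D3:**
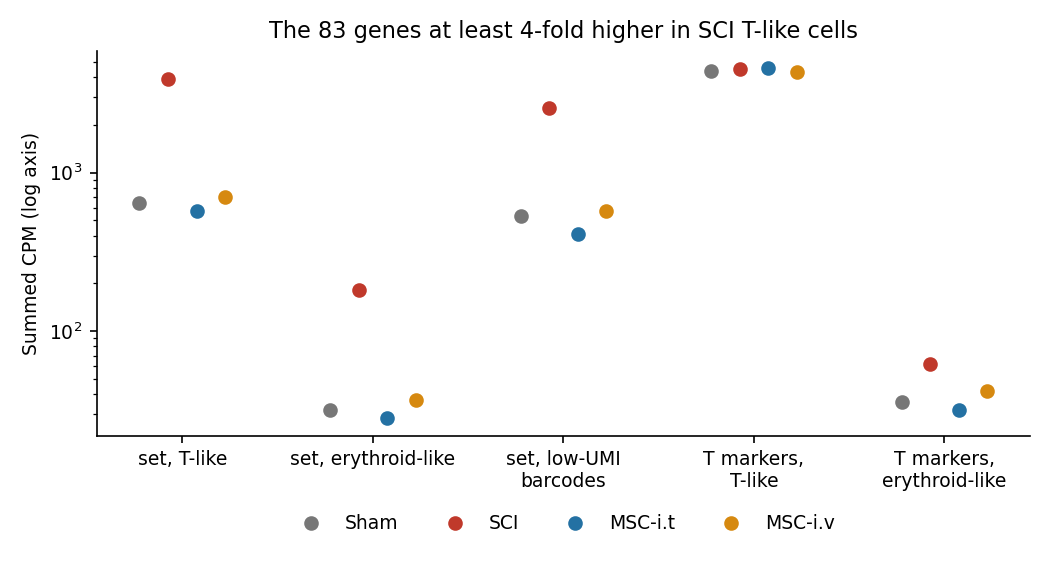
Summed CPM (log axis) in each library of the 83 genes at least 4-fold higher in SCI than in Sham T-like cells, in T-like cells, erythroid-like cells and barcodes with 10 to 100 UMIs, and of T cell markers in T-like and erythroid-like cells. The set reaches 3898 CPM in SCI T-like cells and 573 to 707 CPM in the other 3 libraries, while T cell markers in T-like cells differ little.

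MSC-i.t against SCI addresses what cells given into the spinal canal do to blood leukocytes after injury. The MSC-i.t library had a smaller T-like share and larger B-like cluster 6 and monocyte-like shares than SCI, and in its monocyte-like cells most MHC class II genes were higher and most type I interferon genes lower. With Sham in place of SCI, 34 named gene ratios of the cell-treated libraries lay on the other side of 0, 44 others moved beyond counting error and 7 stayed within it.

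T-like cells made up 69.0% (68.0 to 69.9) of MSC-i.t leukocytes, a log2 ratio of -0.15 to SCI, and 0.22 to Sham. Monocyte-like cells made up 5.996% (5.52 to 6.50), a log2 ratio of 0.33 to SCI and -0.98 to Sham. Cluster 21 held 1.55% (1.30 to 1.82), against 0.750% in SCI. NK-like cells made up 5.29% (4.84 to 5.77), with an interval for the log2 ratio to SCI of -0.10 to 0.31. B-like cluster 6 held 14.4% (13.7 to 15.2), against 9.08% in SCI, and cluster 8 held 4.42% (4.01 to 4.86), against 3.88%.

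In monocyte-like cells the MHC class II list had a median log2 ratio of 0.74 to SCI (percentile 100), 1.31 in cluster 12 alone and -0.77 with Sham as the reference. *RT1-Db1* was at 200 CPM (186 to 214) in MSC-i.t and 56.8 CPM in SCI (log2 ratio 1.82), and *RT1-Bb* had a log2 ratio of 1.66. *Ctss* (-0.79) and *Lgmn* (-0.21) were lower. In the same monocyte-like cells the B cell marker *Cd79b* was at 67.4 CPM in MSC-i.t and 41.5 CPM in SCI. *Cd79a* was at 3.33 and 5.78 CPM. The type I interferon list had a median of -0.81, and of -0.15 with Sham as the reference, with *Mx2* at -2.16 and *Herc6* at -1.67, and *Ifi27* closest to SCI (-0.32, or 1.05 with the ratio in erythroid-like cells subtracted). The cytotoxic list was higher, with a median of 1.51, and of 0.17 with Sham as the reference. *Nkg7* had 87 UMIs in MSC-i.t and 2 in SCI (log2 ratio 4.41, 2.51 to 7.48). *Gzma* had 57 and 0, which is 9.27-fold higher at the floor of 3 counts, with an exact lower limit of 7.30-fold. With doublets removed at an equal rate in each library, the log2 ratio of *Gzma* at that floor was -0.06, so no difference was shown there. *S1pr5* (-0.70) and *Zeb2* (-0.54) were lower. T cell marker *Cd3e* was also higher in MSC-i.t monocyte-like cells, at 117 CPM against 46.8 in SCI, and the cytotoxic median was 0.32 in cluster 12 alone. In NK-like cells the cell cycle list had a median of -0.77, from *Mcm5* (-1.48) and *Mcm2* (-1.05) to *Stmn1* (-0.49, or 0.0045 with the ratio in erythroid-like cells subtracted) and *Mcm3* (-0.41). With Sham as the reference this median was -0.010, and *Mcm5* (0.91), *Mcm2* (0.13), *Stmn1* (0.37) and *Mcm3* (0.33) were on the other side of 0. In T-like cells, held by clusters 3, 9 and 5 in similar parts, the glucocorticoid list was lower, with a median of -0.42, and of -0.036 with Sham as the reference. Its lowest members were *Zfp36l2*, at 143 CPM in MSC-i.t and 337 CPM in SCI (-1.23), and *Fkbp5*, at 13.9 and 28.5 CPM (-1.03), and its highest *Errfi1* (0.31) and *Mt1* (0.09). *Zfp36l2* was at 0.0084 once the ratio in erythroid-like cells was subtracted. It was not among the genes beyond free RNA, at 1.72 CPM in MSC-i.t and 4.08 CPM in SCI erythroid-like cells, so this value decides nothing. *Fkbp5* was at 0.19 with Sham as the reference. Against SCI, 16 pairs of a list and a class stood apart as higher and 9 as lower. With Sham as the reference these counts were 5 and 22. With the ratio in erythroid-like cells subtracted 4 were higher, on fewer lists and members.

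Single genes highest over SCI in T-like cells were *Pla2g2a* (1.35), *Ifi27* (1.09), *Tap2* (0.99) and *Hopx* (0.97), and lowest *Cdv3* (-4.61), *Bloc1s3* (-4.49), *Dapk3* (-4.46) and *Rmnd5a* (-4.10). *Pla2g2a*, which leads platelet-like cluster 15, was at -0.92 once the ratio in erythroid-like cells was subtracted, and *Hopx* also leads monocyte-like cluster 21. *Tap2* was at 29.6 CPM (27.9 to 31.4) in MSC-i.t and 14.9 CPM (13.6 to 16.3) in SCI. In NK-like cells *Npy* (2.76), *Fcmr* (2.50), *Tmcc2* (2.25) and *Car2* (1.79) were highest, and *Cdv3* (-5.28), *Basp1* (-5.11), *Dapk3* (-4.25) and *Taf10* (-4.10) lowest. The 4 highest are marked in other cells: *Npy* leads platelet-like cluster 15, *Fcmr* leads B-like cluster 6, and *Tmcc2* and *Car2* were at 921 and 1175 CPM in MSC-i.t erythroid-like cells. Hemoglobin made up 1.12% of UMIs in MSC-i.t NK-like cells and 0.295% in SCI ones. In monocyte-like cells *Il2rb* (3.23), *Bex3* (2.42), *Ccl5* (1.96) and *Cisd3* (1.94) were highest, of which *Il2rb* and *Ccl5* lead NK-like clusters, and *Sap30l* (-4.52), *Cdv3* (-4.43), *Cebpb* (-4.34) and *Dapk3* (-4.04) lowest. With Sham in place of SCI, *Cebpb* (0.21) and *Dapk3* (0.14) in monocyte-like cells were on the other side of 0.

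MSC-i.v against SCI addresses what cells given into a vein do. The MSC-i.v library had T-like and monocyte-like shares close to those of Sham, and a larger share of B-like cluster 6 than any other library. By its median ratio to each of the other 3 libraries, the type I interferon list was higher in T-like cells of MSC-i.v. Its member *Ifi27*, at 272 CPM, was lower than in Sham (773 CPM) and MSC-i.t (430 CPM). As above, the SCI library's own features enter each ratio.

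T-like cells made up 60.4% (59.5 to 61.2) of MSC-i.v leukocytes, a log2 ratio of -0.35 to SCI and 0.03 to Sham. Monocyte-like cells made up 10.8% (10.3 to 11.4), a log2 ratio of 1.19 to SCI and -0.12 to Sham. Cluster 21 held 3.41% (3.10 to 3.75) and cluster 12 7.41% (6.96 to 7.88). NK-like cells made up 4.44% (4.08 to 4.81), with an interval for the log2 ratio to SCI of -0.35 to 0.05. B-like cluster 6 held 18.9% (18.2 to 19.6) and cluster 8 held 4.33% (3.98 to 4.70).

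In T-like cells, held mostly by clusters 3 and 9 in MSC-i.v and by clusters 5 and 9 in SCI, the type I interferon list had a median log2 ratio of 0.31 to SCI and the interferon gamma list one of 0.43, both at percentile 100. T-like cluster 4, led by *Isg15* and *Mx2*, held 6.56% of T-like cells in MSC-i.v and 2.82% in SCI, and its part in these medians was not tested. *Rtp4* was at 26.6 CPM (24.8 to 28.5) in MSC-i.v and 12.2 CPM (11.1 to 13.5) in SCI, a log2 ratio of 1.12. *Rsad2* had a log2 ratio of 1.56, and *Irf7* (-0.20) and *Trim25* (-0.18) were lowest. *Rsad2* is mainly an erythroid-like transcript here, at 244 CPM in MSC-i.v and 358 CPM in SCI erythroid-like cells against 5.46 and 1.85 CPM in T-like cells. Hemoglobin made up 0.504% of UMIs in MSC-i.v T-like cells and 0.168% in SCI ones, but the type I interferon list still stood apart as higher once free RNA was subtracted. *Irf8* (1.13) and *Irgm* (1.09) led the interferon gamma list, whereas *Socs3* (-0.35) and *Psmb8* (-0.27) were lower. Monocyte-like cells went the opposite way for type I interferon genes, with a median of -0.83 to SCI and of -0.086 to Sham. *Cmpk2* (-1.66) and *Mx2* (-1.55) were lowest there, and *Rsad2* (1.16) and *Trim25* (-0.38) highest. The MHC class II list in monocyte-like cells had a median of 1.01 to SCI, with *RT1-Bb* at 2.83, *RT1-Db1* at 2.72, *Lgmn* at 0.02 and *Ctss* at -0.43. In cluster 12 alone this median was -0.02, and with Sham as the reference it was -0.22. In NK-like cells the cell cycle list had a median of -0.60, with *Mcm5* (-1.48) and *Mcm2* (-1.40) lowest and *Ube2c* (2.45) and *Cenpf* (1.51) highest. With Sham as the reference this median was 0.18, and *Mcm5* was at 0.91. Against SCI, 24 pairs of a list and a class stood apart as higher and 8 as lower, and against Sham 9 and 12. With the ratio in erythroid-like cells subtracted, 5 were higher, on fewer lists and members.

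**Figure D4:**
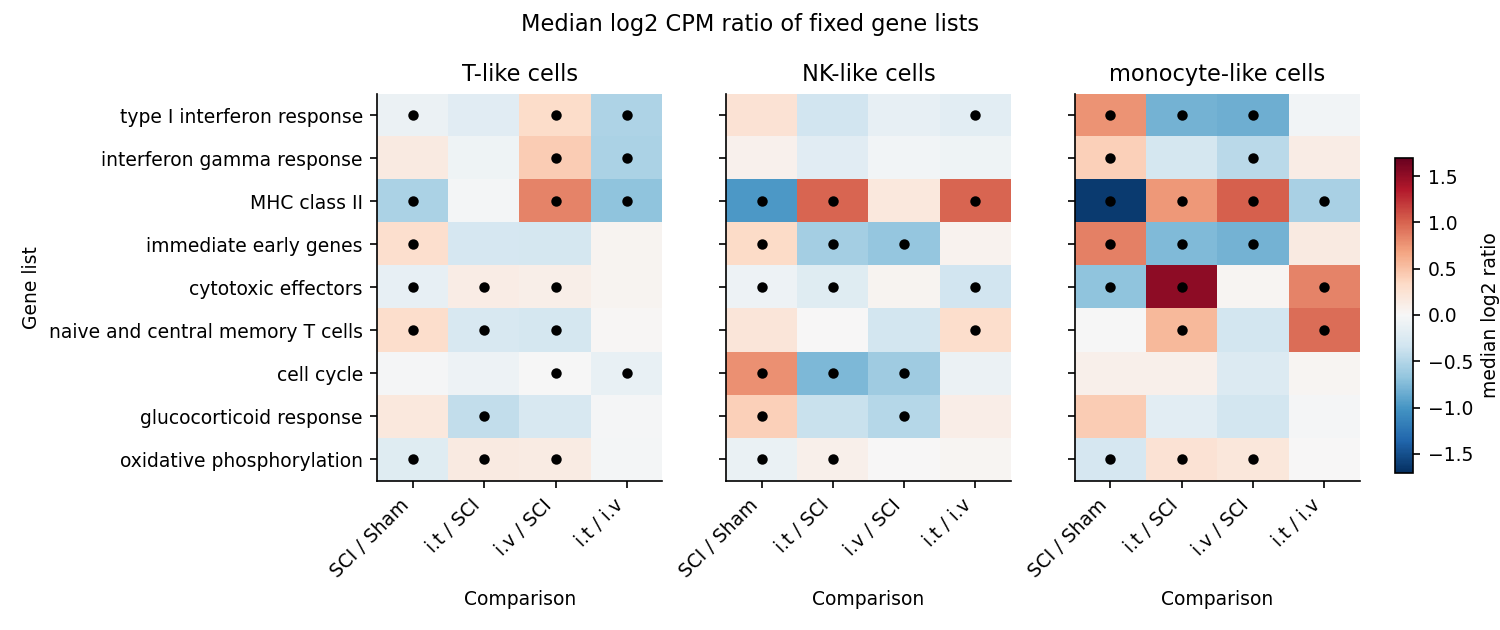
Median log2 CPM ratio (colour) of 9 gene lists in T-like, NK-like and monocyte-like cells for 4 comparisons; a dot marks a median at or beyond the 1st or 99th percentile of 10000 matched random lists. MHC class II in monocyte-like cells runs from -1.62 in SCI over Sham to 1.01 in MSC-i.v over SCI.

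The single genes highest over SCI in T-like cells were *Pla2g2a* (1.35), *S100a4* (1.30), *Fcer1g* (1.17) and *Tyrobp* (1.16), the last a myeloid and NK gene that went to -2.82 or lower once free RNA was subtracted. *Fcer1g* also leads monocyte-like cluster 12. *Dapk3* (-4.28), *Cenpb* (-4.18), *Sap30l* (-4.16) and *Pura* (-4.05) were lowest. *S100a4* was at 138 CPM (134 to 142) in MSC-i.v and 56.0 CPM (53.5 to 58.7) in SCI. In NK-like cells *Car2* (1.19), *Pla2g2a* (1.05), *Rnf13* (0.99) and *Rce1* (0.94) were highest, although *Pla2g2a* was at -0.53 in T-like and -0.84 in NK-like cells once the ratio in erythroid-like cells was subtracted, and *Pura* (-4.51), *Basp1* (-4.25), *Dapk3* (-4.23) and *Sap30l* (-3.95) lowest. In monocyte-like cells *RT1-Ba* (2.18) and *Tmcc2* (1.99, or -0.26 with free RNA subtracted) followed *RT1-Bb* and *RT1-Db1*, and *Dapk3* (-4.65), *Cebpb* (-4.59), *Sap30l* (-3.91) and *Rnf149* (-3.86) were lowest.

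MSC-i.t against MSC-i.v addresses whether the route and dose of the cells matter, and it does not involve the SCI library. The MSC-i.t library had fewer monocyte-like cells than MSC-i.v and a larger T-like share. In its T-like cells most interferon-response genes were lower, and in its NK-like cells most cytotoxic genes. Route and dose differed together, so neither can be taken alone, and median depth was 5523.5 UMIs per cell in MSC-i.t and 3668 in MSC-i.v.

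T-like cells had a log2 ratio of shares of 0.19 (0.14 to 0.24) and monocyte-like cells one of -0.85 (-0.998 to -0.71). The NK-like share had a log2 ratio of 0.25 (0.08 to 0.43), which was -0.07 when every cell was thinned to 500 UMIs. B-like cluster 6 held 14.4% of MSC-i.t and 18.9% of MSC-i.v leukocytes. T-like cluster 4, led by *Isg15*, *Mx2* and *Usp18*, held 1.98% (1.71 to 2.29) in MSC-i.t and 3.96% (3.62 to 4.31) in MSC-i.v.

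In T-like cells the type I interferon list had a median log2 ratio of -0.53, lower than in every matched random list, and 26 of its 29 members were lower in MSC-i.t. *Isg15* was at 33.7 CPM (31.8 to 35.6) in MSC-i.t and 70.3 CPM (67.3 to 73.4) in MSC-i.v, against 48.9 in Sham and 39.97 in SCI, though its log2 ratio of MSC-i.t over MSC-i.v was 0.35 once the ratio in erythroid-like cells was subtracted. *Rtp4* had a log2 ratio of -1.11, whereas *Ifi27* (0.66) and *Bst2* (0.20) were higher. The interferon gamma list also had a median of -0.53. *Socs1* was at 6.57 CPM (5.77 to 7.44) in MSC-i.t and 19.6 CPM (18.0 to 21.3) in MSC-i.v, a log2 ratio of -1.58, and *Irgm* had one of -1.15, or 0.28 with the ratio in erythroid-like cells subtracted, with *Tap2* (0.84) and *Socs3* (0.24) on the other side. MHC class II genes had a median of -0.69, from *RT1-Bb* (-2.12) and *RT1-Ba* (-1.15) to *Lgmn* (-0.24) and *RT1-DOb* (-0.16). *RT1-Bb* and *RT1-Ba* also lead B-like cluster 6, and *RT1-Bb* was at only 1.22 CPM in MSC-i.t and 5.29 CPM in MSC-i.v T-like cells. The B cell activation list was at -0.50 in the same cells, and cluster 6 held 14.4% of leukocytes in MSC-i.t and 18.9% in MSC-i.v. Once the ratio in erythroid-like cells was subtracted, the class II list no longer stood apart there. Only members with enough UMIs in erythroid-like cells had a value, so this does not show that the difference went away. NK-like cells were held in about equal parts by clusters 14 and 20 in MSC-i.t and more by cluster 14 in MSC-i.v. Their cytotoxic list had a median of -0.32, with *S1pr5* at -0.93 and *Zeb2* at -0.67, and *Klrk1* (0.14) and *Hopx* (0.12) highest. Cluster 20 also scored for T cell markers, and its part in this NK-like median was not tested. Monocyte-like cells had a cytotoxic median of 0.85, with *Gzma* (4.50) and *Gzmm* (2.55) highest and *Cst7* (-0.77) and *Id2* (-0.28) lowest. That median was 0.08 in cluster 12 alone, and with doublets removed at an equal rate *Gzmm* was at -0.15 and the ratio of *Gzma* was smaller. Their MHC class II median was -0.55, and 0.75 in cluster 12 alone. In all, 7 pairs of a list and a class stood apart as higher in MSC-i.t and 23 as lower. With the ratio in erythroid-like cells subtracted 7 were lower, on fewer lists and members.

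**Figure D5:**
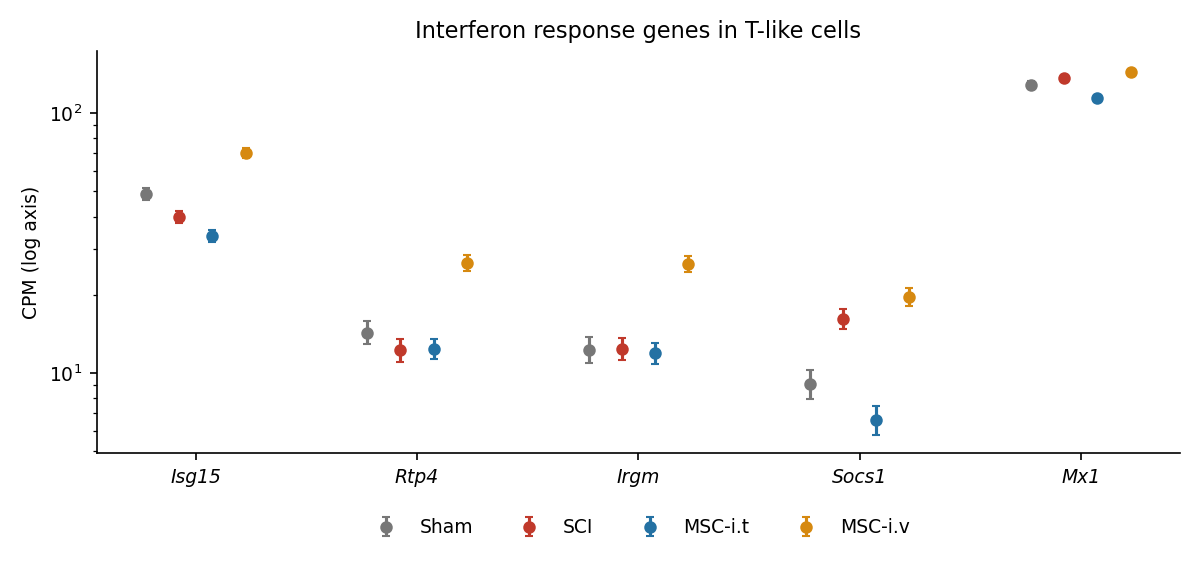
Levels of 5 interferon response genes in T-like cells (CPM, log axis) in the 4 libraries, with exact 95% Poisson intervals. MSC-i.v is highest for all 5, which were picked after their values were seen, at 70.3 CPM for *Isg15* against 33.7 to 48.9 in the others, whereas *Ifi27*, *Bst2* and *Tap2*, which are not drawn, are at 272, 47.8 and 16.5 CPM in MSC-i.v and 430, 54.7 and 29.6 CPM in MSC-i.t.

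The named genes with the largest ratios in T-like cells were *Fxyd7* (0.87), *Tap2*, *Pomp* (0.81) and *Klrb1c* (0.78) on the higher side, and *Dpt* (-2.11), *Glrx5* (-1.60), *Socs1* and *Rab2a* (-1.46) on the lower. *Dpt* was at 3.71 CPM (3.12 to 4.37) in MSC-i.t and 15.96 CPM (14.6 to 17.5) in MSC-i.v, and *Glrx5*, which was abundant in erythroid-like cells, had a log2 ratio of -1.43 there too. In NK-like cells *Fcmr* (2.80), *Ankrd46* (1.28) and *Pomp* (1.16) were among the highest, though *Fcmr* leads B-like cluster 6 and had a log2 ratio of 0.83 with doublets removed at an equal rate, and *Esyt2* (-1.72), *Sys1* (-1.43), *Scand1* (-1.31) and *Desi2* (-1.26) lowest. In monocyte-like cells *Rgcc* (1.96), *Il2rb* (1.85), *Gata3* (1.76) and *Plcg1* (1.74) were highest, of which *Rgcc*, *Il2rb* and *Gata3* lead T-like or NK-like clusters. *Cebpd* was at 49.0 CPM (42.3 to 56.4) in MSC-i.t and 153 CPM (143 to 163) in MSC-i.v, a log2 ratio of -1.64, and *Mtrf1l* (-1.64), *Milr1* (-1.56) and *Scand1* (-1.40) followed, but with the ratio in erythroid-like cells subtracted *Scand1* was at 1.01 in NK-like and 0.92 in monocyte-like cells.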

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

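The tests of whole-library differences, of leukocytes alone and of depth below were chosen only after the result was seen, as was the use as tests of free RNA subtraction, the UMI minimum and per-cell marker scores, which were planned as settings; clustering without SCI-shifted genes and the test without cluster 4 were added after the data were seen, with bounds set before their own values were known.

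Between the routes, 5 gene lists had medians on opposite sides of Sham in the MSC-i.t and MSC-i.v libraries, each apart from matched random lists. These differences were not tested, since each route has 1 library. In T-like cells the median log2 ratio of MSC-i.t over MSC-i.v was -0.53 for type I interferon response, -0.50 for B cell activation and -0.86 for hemoglobin and erythroid transcripts. In monocyte-like cells it was -0.20 for the anti-inflammatory and resolution list and 1.03 for the T cell activation, regulation and inhibition list. The same monocyte-like cells differed in T cell markers, with *Cd3e* at 117 CPM in MSC-i.t and 38.3 in MSC-i.v, *Cd3d* at 154 and 65.9, and *Lck* at 69.0 and 31.4. Barcodes with 10 to 100 UMIs, the source of the free RNA profile, were also examined. There the genes at least 4-fold higher in SCI T-like cells had a median log2 ratio of 2.38 over Sham, from the 17 members with enough UMIs. Because these genes were picked in T-like cells, whose free RNA such barcodes can hold, this is not separate evidence.

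The 83 genes at least 4-fold higher in SCI than in Sham T-like cells had medians of 2.31 in NK-like, 2.30 in monocyte-like and 2.43 in erythroid-like cells, the last from 20 members. A cause in the depth of the cells is argued against by a median of 0.10 in T-like cells of MSC-i.v over Sham, libraries further apart in depth than SCI and Sham. A response of the leukocytes alone is argued against by erythroid-like cells, where the summed level of the set, less the free RNA that T cell markers allow for, still had a log2 ratio of 2.28. That 2.28 is what a difference of the whole SCI library, in handling, chemistry or processing, would need, so this is a candidate explanation. A response to the injury that reaches all blood cells stays open, since group and library coincide.

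The lower type I interferon list in T-like cells of MSC-i.t than of MSC-i.v had a median of -0.53. Free RNA from other cells is argued against, as the median was -0.49 once it was subtracted. Without interferon-led cluster 4 the median was -0.38, so the larger share of that cluster in MSC-i.v may account for part of the difference. In erythroid-like cells the 8 members beyond free RNA had a median of -0.52, running from -1.42 to 0.24, too wide to decide for or against a difference of the whole libraries. Route and dose of the cells, which the design varies together, remain open and untested.

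The lower share of monocyte-like cells in SCI than in Sham had a log2 ratio of -1.31. The UMI minimum is argued against as its cause by a ratio of -1.17 at 250 UMIs. Clusters shaped by genes shifted in SCI T-like cells are argued against by -1.27 when cells were clustered without those genes. Genes shifted in SCI monocyte-like cells alone were not left out there, so that value does not speak to them. Monocyte-like cells hidden in unnamed clusters are argued against by -1.14 when each cell was classed by its own marker score. What may stay behind these values is the injury, the time of the blood draw or the handling of 1 library, and none of them could be tested.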

How the results depend on the processing

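Chosen only after the data were seen were Sham in place of SCI, an equal doublet rate, clustering without SCI-shifted genes, both subtractions of the ratio in erythroid-like cells and cluster 12 alone; the other alternatives were planned. No paired analysis was possible because each group had 1 library. Ratios of genes, shares and neutrophils are called moved when they left the 95% counting interval of the reported value, and reversed when they changed sign where that interval excluded 0. A list moved when it stood apart from random lists under only one of the settings, and reversed when it stood apart on the other side. A count of lists moved when it differed by more than 1.5 times. For the values below the cause was not tested.

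Over all alternatives, 141 share ratios kept their value within counting error, 15 moved and 6 reversed. All 12 stayed within it at 250 and 1000 UMIs, a mitochondrial limit of 10%, resolutions of 0.5 and 2, no doublet removal, an equal doublet rate, variable genes within libraries and clustering without SCI-shifted genes. Over all alternatives the log2 ratio of SCI over Sham ran from 0.30 to 0.49 for T-like, from -0.58 to -0.14 for NK-like and from -1.35 to -1.14 for monocyte-like shares. For MSC-i.t over MSC-i.v it ran from 0.14 to 0.25, from -0.23 to 0.43 and from -1.03 to -0.72. Of gene ratios, 1451 were kept, 202 moved and 58 reversed, and of list medians 2285, 388 and 27. The kept gene ratios include 172 under a filter of 20 UMIs and 130 under one of 100. A count filter leaves a gene's own ratio as it is, so these could not change and are no support. Of counts of lists, 59 were kept and 17 moved, and of neutrophil ratios 30 and 14. With all kept cells as denominator, the 20 cluster ratios were kept. Of the 24 genes per comparison that the rule names, 15 to 17 were also named with a filter of 20 UMIs and 16 to 19 with one of 100. TMM scaling and DESeq2 size factors each moved 9 gene ratios and reversed none. TMM scaling shifts every log2 ratio of a class and comparison by the same amount, so it could not move a list. The 300 list medians and 8 counts of lists kept under it were therefore fixed in advance.

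With a library-specific UMI minimum the share ratio moved to 0.32 for T-like cells in SCI over Sham, -0.26 for T-like cells in MSC-i.v over SCI and 0.14 for T-like cells in MSC-i.t over MSC-i.v. With the class taken from per-cell marker scores it moved to 0.30 for T-like cells and -0.58 for NK-like cells in SCI over Sham, 0.12 for monocyte-like cells in MSC-i.t over SCI, 0.21 for NK-like cells in MSC-i.v over SCI and -0.23 for NK-like cells and -1.03 for monocyte-like cells in MSC-i.t over MSC-i.v. With all kept cells as denominator it moved to 0.49 for T-like cells in SCI over Sham, -0.22 for T-like cells in MSC-i.t over SCI, -0.47 for T-like cells in MSC-i.v over SCI and 0.25 for T-like cells in MSC-i.t over MSC-i.v. With cells thinned to 500 UMIs it moved to -0.20 for NK-like cells in MSC-i.t over SCI and -0.071 for NK-like cells in MSC-i.t over MSC-i.v. Of these, the NK-like ratios of MSC-i.t over MSC-i.v by marker score and in thinned cells were reversed, so the side of that ratio depends on these settings, depth per cell among them.

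Neutrophil-like cells per 1000 lymphocytes rest on 5 to 29 cells per library. They moved to 0.115 in MSC-i.t at 250 UMIs, to 0.125 in MSC-i.t and 1.73 in MSC-i.v with a library-specific minimum and to 1.48 in Sham and 0.453 in MSC-i.t at resolution 0.5. At resolution 2 they moved to 9.68 in Sham, 2.14 in SCI, 4.01 in MSC-i.t and 5.64 in MSC-i.v, by marker score to 1.17 in Sham and 0.11 in MSC-i.t, and in thinned cells to 7.5 in Sham, 2.46 in MSC-i.t and 4.43 in MSC-i.v.

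With Sham in place of SCI, share ratios became 0.22 for T-like cells, -0.18 for NK-like cells and -0.98 for monocyte-like cells in MSC-i.t, 0.027 for T-like cells, -0.44 for NK-like cells and -0.12 for monocyte-like cells in MSC-i.v, of which those for NK-like cells moved and the others reversed. Genes of MSC-i.t that reversed were at -0.57 for *Pla2g2a*, -0.84 for *Ifi27*, -0.53 for *Hopx* and 0.19 for *Fkbp5* in T-like cells. In NK-like cells they were at -0.19 for *Npy*, -0.25 for *Tmcc2*, -0.34 for *Car2*, 0.33 for *Mcm3*, 0.37 for *Stmn1*, 0.91 for *Mcm5* and 0.13 for *Mcm2*. In monocyte-like cells they were at -0.036 for *Ccl5*, 0.21 for *Cebpb*, 0.14 for *Dapk3*, -1.19 for *RT1-Db1*, -1.68 for *RT1-Bb* and 0.056 for *S1pr5*. Genes of MSC-i.v that reversed were at -0.56 for *Pla2g2a*, -0.17 for *Fcer1g*, -0.17 for *Tyrobp*, 0.12 for *Dapk3*, 0.083 for *Sap30l* and 0.20 for *Trim25* in T-like cells. In NK-like cells they were at -0.93 for *Car2*, -1.01 for *Pla2g2a*, -0.20 for *Rnf13*, 0.037 for *Sap30l* and 0.91 for *Mcm5*. In monocyte-like cells they were at -0.51 for *RT1-Bb*, -0.28 for *RT1-Db1*, -0.057 for *RT1-Ba*, -0.24 for *Tmcc2*, -0.68 for *Rsad2* and 0.32 for *Ctss*. Lists of MSC-i.t that reversed were at -1.25 for neutrophil granules and -0.49 for hemoglobin in T-like cells. In NK-like cells they were at -0.48 for hemoglobin. In monocyte-like cells they were at -0.77 for MHC class II. Lists of MSC-i.v that reversed were at 0.18 for cell cycle and -1.63 for hemoglobin in NK-like cells. In monocyte-like cells they were at -0.27 for neutrophil granules, -0.22 for MHC class II and -0.048 for oxidative phosphorylation. Lists apart were 5 higher and 22 lower for MSC-i.t and 9 higher for MSC-i.v.

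Subtracting the ratio of the same libraries in erythroid-like cells is partly void, because part of the RNA counted there is free RNA of leukocytes. It was therefore also run on genes beyond free RNA alone. In both forms only genes with at least 20 UMIs in erythroid-like cells gave a value, so lists lost members. *Hopx*, *Zfp36l2*, *Stmn1*, *Irgm* and *Scand1* below are not among genes beyond free RNA, so their leukocyte difference may have been subtracted from itself. Over all genes, reversed gene ratios of SCI over Sham were 0.44 for *Pla2g2a* and 0.11 for *Hopx* in T-like cells and -0.17 for *Jund* in monocyte-like cells. Those of MSC-i.t over SCI were -0.92 for *Pla2g2a* and 0.0084 for *Zfp36l2* in T-like cells, 0.0045 for *Stmn1* in NK-like cells and 1.05 for *Ifi27* in monocyte-like cells. Those of MSC-i.v over SCI were -0.53 for *Pla2g2a* in T-like cells and -0.84 for *Pla2g2a* in NK-like cells. Those of MSC-i.t over MSC-i.v were 0.35 for *Isg15* and 0.28 for *Irgm* in T-like cells, 1.01 for *Scand1* in NK-like cells and 0.92 for *Scand1* in monocyte-like cells. Reversed list medians of SCI over Sham were 0.12 for oxidative phosphorylation in T-like cells, 0.25 for oxidative phosphorylation in NK-like cells and 0.71 for neutrophil granules in monocyte-like cells. Reversed medians of MSC-i.t over SCI were 0.11 for oxidative phosphorylation in T-like cells, 0.050 for oxidative phosphorylation and -1.09 for platelet transcripts in NK-like cells and -0.95 for platelet transcripts in monocyte-like cells. Reversed medians of MSC-i.v over SCI were -0.19 for oxidative phosphorylation in T-like cells, -1.07 for platelet transcripts in NK-like cells and -0.90 for neutrophil granules in monocyte-like cells. Reversed medians of MSC-i.t over MSC-i.v were 0.98 for neutrophil granules in monocyte-like cells. Lists apart were 5 higher and 7 lower for SCI over Sham, 4 higher for MSC-i.t over SCI, 5 higher for MSC-i.v over SCI and 7 lower for MSC-i.t over MSC-i.v. On genes beyond free RNA, reversed gene ratios of SCI over Sham were 0.44 for *Pla2g2a* in T-like cells and -0.17 for *Jund* in monocyte-like cells. Those there of MSC-i.t over SCI were -0.92 for *Pla2g2a* in T-like cells and 1.05 for *Ifi27* in monocyte-like cells. Those there of MSC-i.v over SCI were -0.53 for *Pla2g2a* in T-like cells and -0.84 for *Pla2g2a* in NK-like cells. Those there of MSC-i.t over MSC-i.v were 0.35 for *Isg15* in T-like cells. Reversed medians there of MSC-i.t over SCI were -1.09 for platelet transcripts in NK-like cells and -0.95 for platelet transcripts in monocyte-like cells. Likewise reversed medians there of MSC-i.v over SCI were -1.07 for platelet transcripts in NK-like cells. Lists apart there were 1 higher and 5 lower for SCI over Sham, 4 higher and 3 lower for MSC-i.t over SCI, 5 higher and 3 lower for MSC-i.v over SCI and 2 higher and 4 lower for MSC-i.t over MSC-i.v.

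With free RNA subtracted, reversed ratios were -2.82 for *Tyrobp* in T-like cells and -0.26 for *Tmcc2* in monocyte-like cells for MSC-i.v over SCI, the first an upper bound because none was left in MSC-i.v. At an equal doublet rate, *Gzmm* of monocyte-like cells reversed to -0.15 in MSC-i.t over MSC-i.v. The value of *Gzma* there, MSC-i.t over SCI, was -0.060, but with 0 UMIs in SCI it is a lower bound, so although it is counted above among the reversed ratios it shows no reversal, only that a difference was no longer shown. The hemoglobin list in NK-like cells, MSC-i.t over MSC-i.v, reversed to -0.79 at an equal doublet rate, -0.55 at 1000 UMIs and -0.76 without doublet removal. For MSC-i.t over MSC-i.v, the MHC class II list of monocyte-like cells reversed to 0.75 in cluster 12 alone, and the count of lists apart and lower moved to 15 with the mean over cells.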

Other observations

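No test in this part was planned; all values here were picked after they were seen and none is explained. T-like cluster 11 held 508 cells with a median mitochondrial share of 0.144% of UMIs, against 4.15% in T-like cluster 3. It made up 1.87% of leukocytes in Sham, 2.11% in SCI, 1.89% in MSC-i.t and 0.296% in MSC-i.v. Plasmacytoid dendritic-like cells numbered 16 in Sham, 1 in SCI, 13 in MSC-i.t and 29 in MSC-i.v. Platelet markers made up 0.0591% of kept UMIs in Sham, 0.0266% in SCI, 0.0428% in MSC-i.t and 0.0371% in MSC-i.v.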
